A study of Mus musculus with 16 samples.

How the data were processed

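Chromatin from the occipital cortex of fasted and ad libitum fed mice was sonicated and immunoprecipitated with an antibody against beta-hydroxybutyrylated H3K9, per the labels' protocols. The labels put 4 immunoprecipitated and 4 input libraries in each feeding state, 16 in all. Bowtie2, MACS2 and the build mm10 are named in the submitters' processing notes, without versions or roles. The authors deposited 2 lists of regions, per the file headers with chromosome, start, end, name and log-LR. The deposited log-LR is used here as a score, a log likelihood ratio for each region. Its log base, its cutoff, any filter, the depth scaling and whether the libraries of a group were pooled are not given in the sources used here. The lists hold no counts and no value per library, so the depth is unknown and no test between mice was possible. A difference in depth, scaling or immunoprecipitation yield between the groups would move the number of regions in each direction.

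Starts were taken as counted from 0, since the smallest width was exactly 120 bp on that reading, and coordinates are given from 1. Genes came from a RefSeq table of assembly GRCm38.p6, the build called mm10, with 49939 genes. The table has no strand, exons or sequence. The planned promoter window was therefore replaced by 1 kb around either end of a gene, and exons and introns were not separated. The planned tests on fold change and on the authors' FDR used the log-LR in their place, and GC content was not analysed here.

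Each region's centre was placed within 1 kb of a gene end, inside a gene, or in intergenic DNA. The same was done for 1000 shuffles, which moved each region within its chromosome and kept its width, with a two-sided permutation p. Shuffles spanned each chromosome from the first to the last annotated gene, since assembly gaps were not in the table. A first run of these shuffles used another seed. The seed was then changed so that the reported value and its alternatives share their shuffles, which moved the ratio only in the third digit. Median log-LR was compared between gene-end and other regions with 100000 permutations. An earlier run of its alternatives used 10000. Regions are not independent replicates of the mice.

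Protein-coding genes with a region overlapping the 1 kb around an end were counted for 13 pathway lists, 9 cell type marker lists and the olfactory receptors, all fixed before the data were examined. Each list was compared with all other protein-coding genes by a two-sided Fisher exact test with Benjamini-Hochberg adjustment over the 23 lists, at an adjusted threshold of 0.05. The rule for named genes, fixed at the same time, took the genes nearest to the 10 regions of smallest FDR and of largest fold, here the 10 of highest log-LR, and up to 4 members of each list, here those of highest log-LR. Some genes that this rule takes are not reported here. Other genes and regions named, including those on X, in arrays and in the closing section, were chosen after their values were seen. The list step was tested on simulated data, in which 40% of a list of 25 genes was given a region among 21883 genes. The planted list was called in 15 of 20 simulated sets, and 1 of 440 unplanted lists was called. All simulated lists were genes drawn at random. These counts therefore do not give the power for other list sizes or smaller shares, or the false-call rate for lists of active genes. Intervals are 95% Wilson intervals for shares, and cover counting error only.

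The settings varied, as fixed before the data were examined, were windows of 500 bp and 3 kb, other overlap rules (with 200 shuffles for the rule that most of the region lie in the window), protein-coding ends only, regions in the gene body, and merging of regions within 1 kb. Settings chosen after seeing the data were log-LR limits of 5 and 10, leaving out arrays and contigs, shuffles within 50 kb of a protein-coding gene, random lists matched on gene length, autosomal genes only, and a background without receptor families and unnamed genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.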

Results

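Histone H3 lysine 9 beta-hydroxybutyrylation, a histone mark whose acyl group is derived from the ketone body beta-hydroxybutyrate, was profiled by chromatin immunoprecipitation and sequencing in the occipital cortex of C57BL/6J mice at postnatal day 35. Mice were fasted for 48 h or fed ad libitum, and the design asks where the mark differs between these states. The labels describe 16 libraries, 4 immunoprecipitated and 4 input libraries per feeding state. The values analysed here were the authors' 2 deposited region lists, with a log likelihood ratio (log-LR) for each region as its own value. The lists carry no value per library, so the depth is unknown, and no fold change or replicate spread could be computed. The p-values below compare positions or genes within a list and do not measure the spread between mice.

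The deposited difference ran almost wholly in the fasted direction. The list of regions enriched in fasted mice held 8404 regions covering 2.06 Mb of the mm10 genome, and the list for ad libitum mice held 1 region. Fasted regions were short, with a median width of 205 bp and quartiles of 154 and 286 bp. Their log-LR had a median of 4.96 and quartiles of 4.17 and 6.28. The ad libitum region, at chromosome 3, 58665865 to 58666096, had a log-LR of 27.1 and lay inside the pseudogene LOC100417266. Its nearest protein-coding gene was Siah2, a ubiquitin ligase gene 8853 bp away. Among fasted regions, 163 had a log-LR at or above 27.1.

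Fasting-enriched regions gathered at the ends of genes. Of the 8221 regions on assembled chromosomes, 2779 (33.8%, 95% Wilson interval 32.8 to 34.8) had their centre within 1 kb of an annotated gene end, against a mean of 6.28% when the regions were shuffled. The ratio was 5.38, with a two-sided permutation p of 0.0020, the smallest that 1000 shuffles can give. It was 2.75 with a window of 3 kb and 2.23 among regions with a log-LR of at least 10, of which 13.8% lay at a gene end (permutation p = 0.0020 for both). For protein-coding genes the share was 29.1% against 3.07%, a ratio of 9.48 (permutation p = 0.0020). Regions inside genes and over 1 kb from any end made up 28.6% against 44.0% in shuffles, and intergenic regions 37.6% against 49.8%, both with a permutation p of 0.0020. The most filled distance class within 1 kb was 250 to 500 bp from a protein-coding gene end, with 12.4% of regions. The gene table gives no strand, so transcription start and end sites were not separated. With shuffles kept within 50 kb of a protein-coding gene, the ratio for all gene ends was 4.17 (permutation p = 0.0020). The lists hold no regions that carry the mark alike in both feeding states. Whether fasting-enriched regions lie at gene ends more often than marked regions in general could therefore not be tested.

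**Figure D1:**
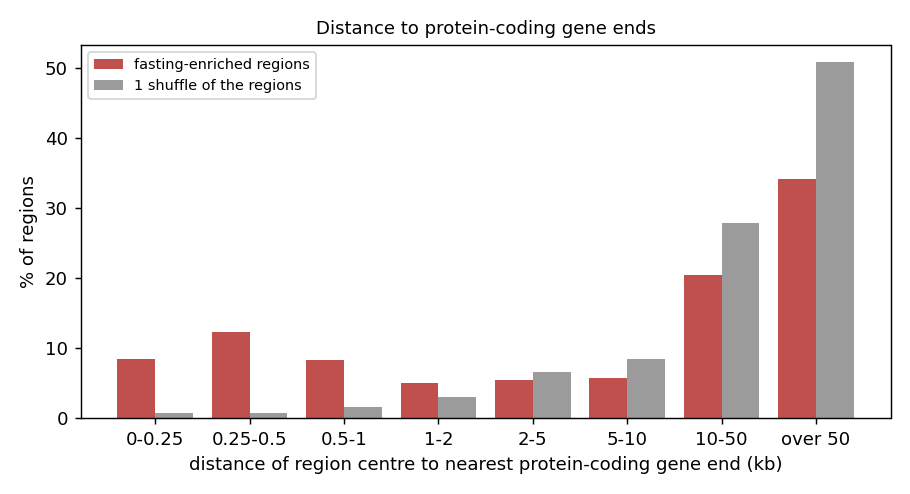
Percent of fasting-enriched regions on assembled chromosomes (red) and of 1 shuffle of them (gray), by distance of the region centre to the nearest protein-coding gene end in kb. In the class from 250 to 500 bp the regions reached 12.4% and the shuffle 0.815%.

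The regions with the highest log-LR were not at protein-coding gene ends. None (0) of the 100 highest lay within 1 kb of one, while 88 lay on unplaced contigs or in dense arrays, defined after the data were seen as 5 or more regions with gaps of at most 20 kb. Of the 10 highest, 8 lay between positions 3000223 and 3025964 of chromosome 9. The nearest annotated gene there, the microRNA gene Mir101c, was 12.7 to 38.0 kb away. The others were at chromosome 2, 98666646 to 98667256 (log-LR 1371, nearest gene Gm33780 at 35.3 kb), and chromosome 14, 19418544 to 19418974 (log-LR 909.5, nearest gene Gm9637 at 13.5 kb). None of the 10 lay in an annotated gene. The chromosome 9 array held 36 regions with a median log-LR of 512.2 and a maximum of 1498. Another array, at chromosome 8, 123538455 to 123624160, held 64 regions over a cluster with 41 genes for 5S ribosomal RNA, with a median log-LR of 4.64. In all, 51 arrays held 706 regions. On assembled chromosomes 578 regions were in arrays, against a mean of 0.595 and at most 11 in shuffles. Median log-LR was 4.92 at protein-coding gene ends (2391 regions) and 4.93 elsewhere (5830 regions), a difference that did not pass the permutation test (two-sided, p = 0.90).

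**Figure D2:**
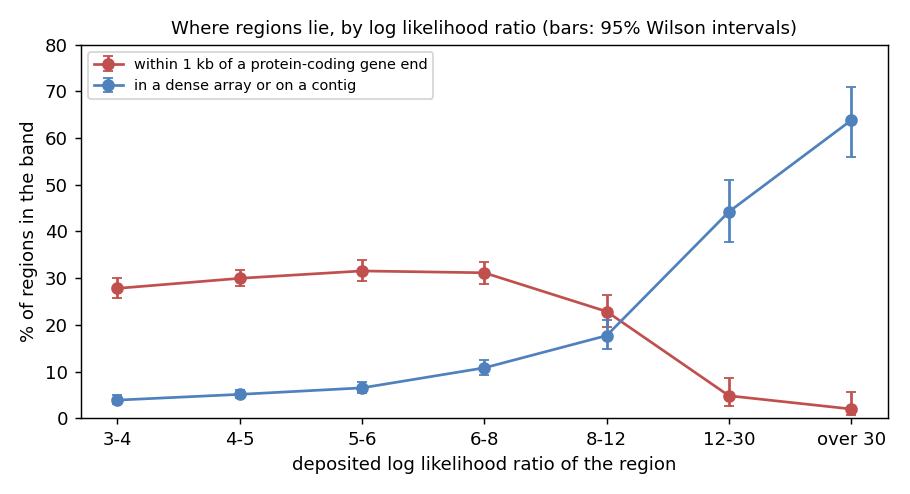
Percent of fasting-enriched regions in each band of log-LR that lay within 1 kb of a protein-coding gene end (red) or in a dense array or on a contig (blue), with 95% Wilson intervals. The gene-end share was 31.5% in the band from 5 to 6 and 1.97% over 30, while the array and contig share rose from 3.88% to 63.8%.

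At the level of genes, 2608 of 21883 protein-coding genes (11.9%) had a fasting-enriched region overlapping the 1 kb around an end, and 674 of them shared that region with another gene. In 4 of the 23 lists fixed before the data were examined, genes had such a region more often than other genes (two-sided Fisher exact test, Benjamini-Hochberg over 23 lists). Immediate early genes, which neurons induce within minutes of activity, held one in 11 of 23 (odds ratio 6.80, 95% interval 2.71 to 16.9, exact adjusted p = 2.66e-04). They included the transcription factor genes Jun (log-LR 7.24), Nr4a3 (6.48) and Egr4 (5.70), and Ier5 (5.61). For insulin, mTOR and autophagy genes the count was 12 of 30 (odds ratio 4.95, 2.17 to 10.9, exact adjusted p = 6.69e-04). Among these were Igf1r, the insulin-like growth factor receptor gene (log-LR 9.98), Atg12 of the autophagosome pathway (8.65, a region shared with Ap3s1), Tsc1, a brake on mTOR (5.86), and Rptor, an mTOR complex component (5.79). Histone acylation writers and erasers held a region in 10 of 29 (odds ratio 3.90, 1.62 to 8.83, exact adjusted p = 0.00765), including the acetyltransferase genes Crebbp (log-LR 7.05), Kat2b (7.03) and Kat6b (5.77), and the deacetylase gene Hdac3 (6.48, shared with Rell2). For oxidative phosphorylation genes it was 14 of 58 (odds ratio 2.36, 1.19 to 4.39, exact adjusted p = 0.0355). Uqcrfs1 (7.01), Uqcrq (6.24, shared with Gdf9), Ndufb4 (6.96) and Cox7c (6.27), which encode subunits of respiratory complexes, had the highest log-LR there. A region counted for a gene can lie outside it. Those of Atg12 and Hdac3, for example, did so and overlapped Ap3s1 and Rell2. The oxidative phosphorylation call ended under 4 of the 8 alternative settings, the insulin, mTOR and autophagy call at a log-LR of at least 5 (odds ratio 3.20, exact adjusted p = 0.105) and the histone acylation call with a window of 500 bp (odds ratio 3.02, exact adjusted p = 0.0562). The other 3 calls were also compared with 203 genes of 5 lists, a comparison chosen after the data were seen. These were the oxidative phosphorylation, ribosomal protein, synaptic, glycolysis and protein folding lists, taken without a test as used widely in cortex. They include a called list, and 47 of the 203 genes (23.2%) had a region. None of the 3 passed: the odds ratio was 3.04 for immediate early genes (exact adjusted p = 0.0614), 2.21 for insulin, mTOR and autophagy genes (exact adjusted p = 0.104) and 1.75 for histone acylation genes (exact adjusted p = 0.247). With 23 to 30 genes in each of the 3, not passing does not show that the shares are alike.

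The other 9 pathway lists were not called. Ketone body genes held a region in 3 of 10, including Oxct1 (log-LR 4.88), an enzyme gene of ketone body use, and the transporter gene Slc16a6 (5.17, shared with Arsg). Their odds ratio was 3.17 with an interval of 0.529 to 13.9 (Fisher exact test, adjusted p = 0.255). Fatty acid oxidation genes had 4 of 25 (exact adjusted p = 0.718), with Acadl at a log-LR of 5.51 and the regulator genes Ppara at 5.37 and Ppargc1a at 4.85. Glycolysis and glucose transport genes had 5 of 19 (exact adjusted p = 0.198), led by Pkm (7.06, shared with Gramd2) and Gapdh (5.95). Glucocorticoid and FOXO responsive genes had 5 of 24 (exact adjusted p = 0.412), led by Fbxo32 (8.59) and Klf9 (6.98). Circadian clock genes had 3 of 22 (exact adjusted p = 0.852), with Nr1d2, a clock repressor gene, at 10.8. Synaptic genes had 10 of 41 (odds ratio 2.39, exact adjusted p = 0.0966), among them the NMDA receptor gene Grin1 (9.18, shared with Lrrc26), Unc13a (7.26) and Syt1 (6.45). The regions counted for Grin1 and Pkm lay outside these genes and overlapped Lrrc26 and Gramd2. Cytosolic ribosomal protein genes had 12 of 60 (exact adjusted p = 0.198), with Rps29 at 31.7, where the region overlaps the 7SL RNA gene Rn7s1. Protein folding genes had 6 of 25 (exact adjusted p = 0.255), led by Hsp90ab1 (5.62) and Hspa5 (5.61). Visual cortex plasticity genes had 2 of 18 (exact adjusted p = 1), Rtn4 (6.75) and Ntrk2 (4.59). With regions anywhere in the gene body counted, a setting that gives longer genes more room for a region, synaptic genes were called with 19 of 41 (odds ratio 3.92, exact adjusted p = 3.16e-04) and glucocorticoid and FOXO responsive genes with 10 of 24 (3.23, exact adjusted p = 0.0238). Ribosomal protein genes were called at a log-LR of at least 5 (odds ratio 2.83, exact adjusted p = 0.0474) and against random lists matched on gene length (3.10, permutation adjusted p = 0.0138).

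Olfactory receptor genes, a family listed as not active in cortex, held a region in 5 of 1106 (0.452%, odds ratio 0.0317, exact adjusted p = 6.86e-53), of which Olfr982 had the highest log-LR, 6.95. None of the 9 cell type lists was called by the Fisher exact test. Oligodendrocyte markers had 2 of 12, the myelin genes Mbp (6.61) and Cnp (6.52), inhibitory neuron markers 1 of 12 (Dlx2, 4.02) and microglia markers 1 of 11. Excitatory neuron, astrocyte, and endothelial and mural markers had 0 of 11, 0 of 10 and 0 of 12, with upper Wilson bounds of 25.9%, 27.7% and 24.2%. Markers of tissues outside the dissection, namely liver, blood and skeletal muscle, had 0 of 35, with an upper Wilson bound of 9.89% when pooled, below the 11.9% of all genes (unadjusted Fisher exact p = 0.0180, a pooling chosen after the data were seen). Excitatory neuron, astrocyte, and endothelial and mural markers held none either, so the low share is not shown to be particular to tissues outside the dissection. Each list of 10 to 12 genes on its own leaves a wide interval that holds the share of all genes. Of the 23 lists, 6 had an unadjusted exact p under 0.05.

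**Figure D3:**
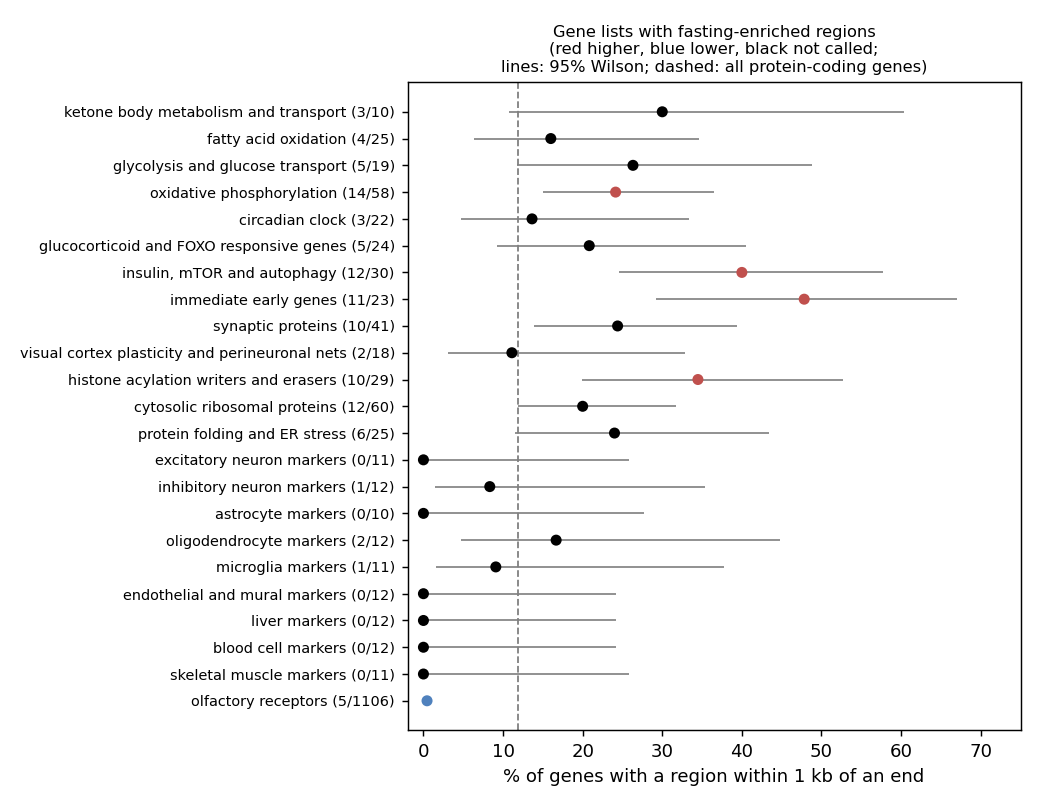
Percent of the genes of each list with a fasting-enriched region within 1 kb of a gene end (horizontal axis), with 95% Wilson intervals and, in brackets, genes with a region over genes in the list. Red lists are higher, blue lower and black not called; the dashed line is the 11.9% of all protein-coding genes, and immediate early genes reach 47.8%.

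Chromosome X stood apart from the autosomes. A region at an end was found for 7 of 966 X genes (0.725%, 95% Wilson interval 0.351 to 1.49), against 2593 of 20661 autosomal genes (12.6%), an odds ratio of 0.0509 (two-sided Fisher exact test, p = 3.47e-44). This comparison was chosen after the data were seen. With regions in the gene body counted, 42 X genes held one and the odds ratio was 0.194 (exact p = 8.54e-40). The 7 genes were Cdk16 (log-LR 6.86), Rbm3 (5.57, a cold-inducible RNA-binding protein gene), Mtmr1 (5.20), Spin2d (4.90), Tab3 (4.67), Nudt10 (4.05) and Mid1 (11.7, within an array). Regions of any location were also sparser on X, at 1.80 per Mb against 3.21 per Mb over the 19 autosomes (range 2.69 to 3.94). That gap was smaller than the one in the share of genes with a region at an end. Chromosome Y held 74 regions, or 0.815 per Mb, and 8 of its 256 protein-coding genes (3.12%) had a region at an end, among them Gm4064 (log-LR 65.5, outside arrays). Of the 74 regions, 29 lay in 1 array, from position 90731029 to 90818415. The labels used here do not give the sex of the mice.

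**Figure D4:**
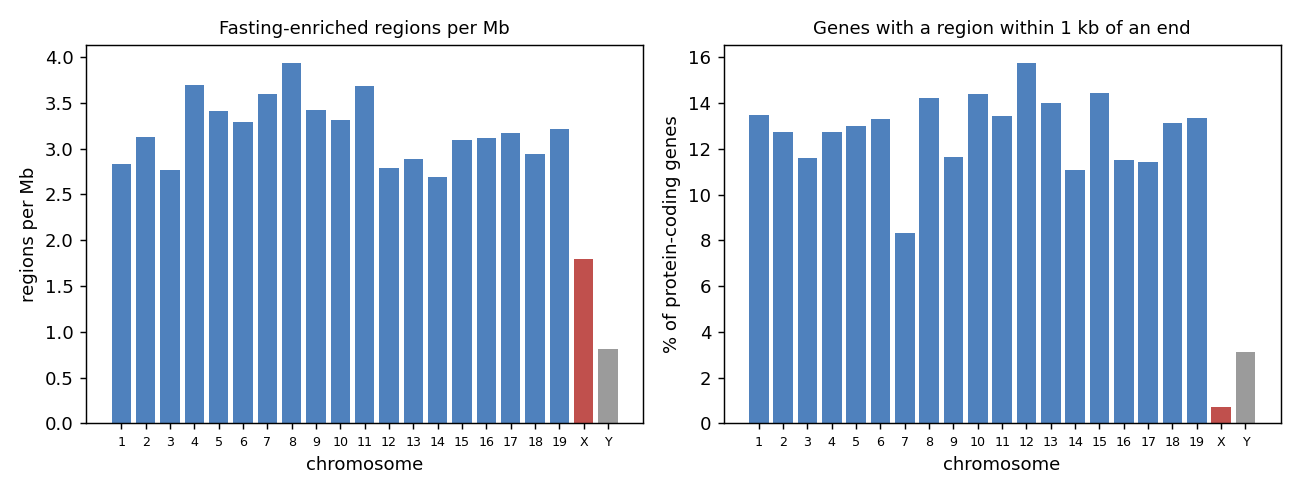
Fasting-enriched regions per Mb of chromosome (left) and percent of protein-coding genes with a region within 1 kb of an end (right), for the autosomes (blue), X (red) and Y (gray). The X gene share is 0.725%, and the autosomes together have 12.6%.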

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

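The comparison of arrays in this part was chosen after the result was seen. Fasting-enriched regions on unplaced and unlocalised contigs, which no gene comparison used, numbered 183, and 110 of them lay on 1 contig, between its bases 669 and 114250. They were picked out as signal in data outside the main comparisons. On that contig the regions covered 50.8% of this span, with a median log-LR of 21.4 and a maximum of 632.4.

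Most of the highest log-LR values fell in dense arrays and on contigs, which held 88 of the 100 highest regions but 673 of the other 8304 (8.10%). Of the 106 regions with a log-LR over 100, 91 lay there. Regions outside reached a log-LR of 1371, so leaving out arrays and contigs does not remove all such regions. Arrays were defined after high values there had been seen, so these counts describe the pattern and test no explanation of it. Multi-copy sequence, which collects many reads at few annotated copies, and a gain of the mark on repeated DNA in fasted mice cannot be told apart, since neither the input libraries nor copy numbers were analysed here.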

How the results depend on the processing

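Alternatives by log-LR limit, by leaving out arrays and contigs, by length-matched lists and by a narrower background were chosen after seeing the data. Merging regions within 1 kb, a setting fixed beforehand, turned the 8404 fasted regions into 7408. The number of fasted regions was 4102 at a log-LR of at least 5 and 491 at 10. Median width was 232 bp at 5 and 201 bp without arrays and contigs. The shifts with log-LR limits and without arrays are ones that the selection itself makes. The enrichment at gene ends passed its test in all settings run, with ratios from 2.23 to 9.48, and the low share of X genes did too, with odds ratios from 0.0443 to 0.194. The log-LR difference of gene ends from other regions became -0.253 at a limit of 5 (permutation p = 5.00e-05) and -3.85 at 10 (permutation p = 0.047), limits that select on the compared value itself, and was 0.0658 without arrays and contigs (permutation p = 0.19), so no difference is drawn from them. Of 183 list results, 173 kept their call or lack of one, 6 lost a call and 4 gained one. In 10 of the 173, from 7 lists without a call (for example fatty acid oxidation, 0.823 at 500 bp), the odds ratio moved to the other side of 1. Oxidative phosphorylation lost its call at 3 kb (odds ratio 2.04), in the gene body (1.58), at a log-LR of 5 (2.56) and without receptor families and unnamed genes (2.06), with exact adjusted p from 0.0785 to 0.270. Insulin, mTOR and autophagy lost it at a log-LR of 5 (3.20, exact adjusted p = 0.105), and histone acylation at 500 bp (3.02, exact adjusted p = 0.0562). Calls were gained in the gene body by synaptic genes (3.92) and glucocorticoid and FOXO responsive genes (3.23), and by ribosomal protein genes at a log-LR of 5 (2.83) and against length-matched lists (3.10). The cause was not tested. No paired analysis was possible because the lists carry no value per library. For the same reason leaving out replicates was not run, and alternatives on FDR, fold, GC and CpG content and on shuffled widths were not run either.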

Other observations

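All tests in this part were chosen after the results were seen. Grouped by the start of their symbol, 3 of 112 gene families had a fasting-enriched region at an end more often than other genes (Fisher exact test, Benjamini-Hochberg over 112). They were the Ube family of ubiquitin-conjugating and ligating enzymes, with 14 of 42 (exact adjusted p = 0.00644) including Ube3a, symbols starting with Vps, many of them vesicle sorting genes, with 12 of 35 (exact adjusted p = 0.0101) including Vps35, and symbols starting with Rab, with 17 of 69 (exact adjusted p = 0.0463). The last group holds Rab GTPase genes such as Rab5a and Rab7 but also Rab11fip2 and Rab11fip3, which encode proteins that bind a Rab GTPase. Symbols of Rab, a number and at most a letter had 15 of 59 (odds ratio 2.53, unadjusted Fisher exact p = 0.00375). The 3 families were also compared with the same 5 lists taken as used widely in cortex, which include the called oxidative phosphorylation list. About 23.2% of the genes of these lists had a region, and none of the 3 families passed (odds ratios 1.66 for Ube, 1.73 for Vps and 1.11 for Rab, exact adjusted p from 0.303 to 0.744). Families with fewer than other genes included the vomeronasal receptors Vmn (0 of 355), the keratins Krt (0 of 53) and the cytochromes P450 Cyp (2 of 99).

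Among short non-coding genes the classes differed in count. Ribosomal RNA genes were overlapped in 14 of 63, against a mean of 0.150 over 20 shuffles, and 13 of these were 5S genes of the chromosome 8 cluster. MicroRNA genes were overlapped in 15 of 1228, against a mean of 0.900 and at most 4. These 15 rest on 12 regions, of which 9 also overlap the 1 kb around a protein-coding gene end, a gathering that the shuffles do not keep. Small nuclear RNA genes were overlapped in 1 of 1004 (shuffled mean 1.15), and small nucleolar RNA genes in 4 of 1340 (mean 1.80, at most 4). Mir132 and Mir212, a pair induced by neuronal activity, shared the region at chromosome 11, 75173301 to 75173831 (log-LR 5.58), and Mir129-2 had a log-LR of 7.76. The 1 small nuclear RNA gene was Rn7sk, for 7SK RNA, with a log-LR of 39.3. Many such genes have near-identical copies. The highest log-LR at a protein-coding gene end outside arrays was 88.1, at Wls, which encodes a Wnt secretion protein, with the region beyond the gene at chromosome 3, 159939495 to 159939634.

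Few X genes had a region at an end. A single X copy that lowers the log-LR of X regions alike would thin gene-end regions and others in like proportion. That holds only if log-LR is spread alike in both. On autosomes, medians outside arrays were 4.89 at gene ends and 4.84 elsewhere, but the highest values lay elsewhere. Outside arrays, X held 6 gene-end regions (0.0352 per Mb, autosomes 0.952) and 241 others (1.41 per Mb, autosomes 2.06). The odds ratio was 0.0539 (95% interval 0.0196 to 0.119, Fisher exact p = 5.81e-31). It does not allow for X having fewer protein-coding genes per Mb than the autosomes together. Counted per gene, without arrays and contigs, the odds ratio of X against autosomal genes was 0.0443. The X gene share and X region density had been seen before this comparison was set up, so its outcome was largely fixed. The values describe a shortfall on X that was larger at gene ends than elsewhere. They do not settle whether a single X copy caused it. A version in which regions away from gene ends hold multi-copy sequence, and so escape the loss, stays open too. The labels give no sex, and no biological explanation was tested.

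The lists held 8404 regions in one direction and 1 in the other. A general lift of the fasted signal, from library scaling or immunoprecipitation yield, could give this at every active gene. Among oxidative phosphorylation and ribosomal protein genes, which most cells use, 22.0% (26 of 118, 95% Wilson interval 15.5 to 30.3) had a region at an end, against 11.9% of other genes. This lies far from all such genes but above the others, and the lists hold only regions past an unstated cutoff. Scaling, yield and a gain of the mark in fasting therefore cannot be told apart here.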
